A study of Pan troglodytes and Macaca mulatta with 12 samples.

How the data were processed

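RNA sequencing was carried out on lymphoblastoid cell lines, which are B lymphocytes immortalised for continued culture. The lines came from 6 chimpanzees and 6 rhesus macaques, each line from a separate individual. Per the labels' protocols, total RNA was taken from cultured cells with a Qiagen RNeasy kit, complementary DNA was end-repaired, fitted with Illumina adapters, size selected on a gel and amplified by PCR, and libraries were read on a Genome Analyzer II. The steps given mark no strand. The series design also names human lines, which were not analysed here.

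The deposited files, 1 per library, hold raw counts per exon as whole numbers, with an exon written as an identifier, an exon number, a chromosome, a start and an end. Only exons with at least 1 count are listed in a file, and an exon missing from a library's file was taken as 0. All 12 files use 1 set of exon names and coordinates, so counts from both species refer to the same exon definitions. The aligner, the counting tool, the genome build and the orthology rules behind those exons are not given in the sources used here. Coordinates are printed as the files give them. Exons of different genes overlap for 168 exons, whose reads cannot be assigned to 1 gene without strand. The files list exons on 23 chromosomes, numbered 1 to 22 plus X. Chromosomes, neighbours, gaps and gene density below are those of this shared set of coordinates. Chromosomes and gene order in each species' own genome were not examined and may differ.

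The files do not pair identifiers with gene names. Of the 16903 gene identifiers, 0 matched the gene name table and 0 matched the RefSeq table, so genes are described by position, and at most 2 identifiers are printed in each direction. The gene lists fixed before the data were examined need symbols and were not run. Chromosomes and runs of neighbouring genes took their place, and this choice was made after the data were seen.

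Library totals ran from 1434241 to 4751954 counts. Exon counts were summed per gene. The main species test was the edgeR 4.0.16 quasi-likelihood test (limma 3.58.1, R 4.3.3) with TMM normalisation and species as the only term. Genes were kept by the default expression filter (a minimum count of 10, a minimum total of 15, in at least 6 libraries), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A difference beyond 2-fold was tested with glmTreat. CPM values (counts scaled to a common library size) were computed from the deposited counts with TMM-scaled library sizes, and log2 CPM used a prior count of 2. Log2 fold changes are chimpanzee minus rhesus macaque throughout. Sex was tested with a fit of 4 groups (species by sex), from the sex given in the labels. Differential exon usage was tested with diffSpliceDGE on exons with at least 10 counts over all libraries, with the Simes method per gene. Chromosome sets were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. A run was defined as at least 4 neighbouring tested genes that all passed the species test with a log2 difference beyond 1 in the same direction. Gene order was shuffled within chromosomes 1000 times for the tests of neighbours. A group at 0 counts was given a floor of 3 counts over its 6 libraries, which covers counting error only, since the reads carry no molecular identifiers.

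The identifiers printed were picked by a rule written before the data were examined: the largest differences per direction among genes past the threshold, with all 6 libraries of one species above all 6 of the other and a mean of at least 2 CPM in the lower species. Without symbols the rule allows 2 per direction. Positions described for exon usage follow the rule's order of the gene's adjusted p, each with the exon of largest difference. Positions of genes at 0 counts in 1 species, of the runs and of the most variable genes were ranked by size, a choice made after the data were seen.

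The fits were tested on simulated counts with the real means and library sizes. Genes were drawn independently of each other and only a small part of them was changed. The shares below need not hold where genes vary together or where many differ, as in the real species comparison. In the simulated species comparison (9520 genes), 89.6% of genes changed 8-fold, 76.6% of those changed 4-fold and 22.4% of those changed 2-fold were called, with 1 false call. In the simulated sex comparison in chimpanzee (9497 genes), 71.4% of genes changed 8-fold, 56.2% of those changed 4-fold and 0% of those changed 2-fold were called, with 4 false calls. In rhesus macaque the shares were 68%, 28% and 2%, with 1 false call. In the simulated exon usage comparison (10014 genes), 77.3% of genes with an exon changed 8-fold and 41.8% of those with an exon changed 4-fold were called and 0% at 2-fold, with 0 false calls. Simulated exons varied between libraries only with their gene and by counting noise. The 0 false calls therefore do not give the error rate in the real counts.

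Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and its Wald test, upper-quartile scaling, limma voom, no expression filter, a filter of 5 CPM in 6 libraries, sex as a covariate, thinning to the smallest library, exons seen in at least 3 libraries of each species, removal of the strongest exon from genes with at least 2 counted exons, removal of the 2 chimpanzee lines with AG titles, males only, a threshold of 0.01, a gene length correction, and leaving out each library in turn. A correction for the number of tested genes within 1 Mb, and fits without rhesus macaque replicates 5 and 6, with or without chimpanzee replicate 1, were added after the data were seen. The GC content part of the length correction needs a genome sequence, not used here, and was not run. Replicate numbers follow the order of the records and pair no samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.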

Results

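Gene expression was measured by RNA sequencing in lymphoblastoid cell lines of 6 chimpanzees (3 females and 3 males) and 6 rhesus macaques (2 females and 4 males), 1 library per individual. Total counts in chimpanzee replicates 1 to 6 were 1434241, 2412430, 2576148, 2543302, 2488153 and 4751954. Total counts in rhesus macaque replicates 1 to 6 were 1801830, 2103199, 2122502, 3352686, 3759443 and 4600137. At least 1 count was found for 119202 exons of 16903 genes, and 9440 genes, which held 99.0% of all counts, had enough counts for testing. The 10 genes with most counts took between 3.18% and 5.09% of a library. Libraries of 1 species resembled each other more than those of the other. The mean Spearman correlation of log2 CPM over genes was 0.896 between chimpanzee libraries, 0.914 between rhesus macaque libraries and 0.702 between the species. The first principal component held 63.5% of the variance and separated the species. The second component held 9.20% and spread libraries of the same species, from -48.1 in chimpanzee replicate 5 to 61.7 in chimpanzee replicate 1 and from -19.9 to 36.1 in rhesus macaque. No pair of libraries of 1 species agreed within counting noise, and the closest pair differed by 15.6 times that noise (chi-square per degree of freedom).

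The first comparison asks which genes are expressed at different levels in the lymphoblastoid cells of the 2 species. Of the 9440 genes tested, 2329 were higher and 2220 were lower in chimpanzee (edgeR quasi-likelihood test, adjusted p under 0.05), together 48.2% of the genes. The median size of the called differences was 2.51-fold. A difference of more than 2-fold passed its own test for 1628 genes, 825 of them higher and 803 lower in chimpanzee. On exons seen in at least 3 libraries of each species, 1254 of 9019 tested genes passed that test. Without the strongest exon 1362 of 8337 did, and thinned to the smallest library 1350 of 8651. In 2557 genes (27.1%) every library of one species lay above every library of the other, which chance gives for 0.216% of genes. Among the 867 genes beyond 2-fold with at least 5 well-counted exons, 839 (96.8%) had every such exon changed in the direction of the gene. The gene's level is the sum of the same exons and these genes were chosen for a large difference. Their agreement is therefore not independent support for the calls. Genes with 1 counted exon were beyond 2-fold in 23.9% of cases, against 16.6% of genes with more exons. With males only, 4 rhesus macaque and 3 chimpanzee libraries, the counts were 1371 higher and 1385 lower.

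Among fully separated genes with a mean of at least 2 CPM in both species, the largest difference towards chimpanzee was in ENSG00000138755, a gene with 4 counted exons on chromosome 4 from 77141647 to 77147686. It stood at 1383 ± 2084 CPM in chimpanzee and 2.79 ± 2.89 CPM in rhesus macaque (SD, n = 6 each), a log2 fold change of 8.90 with a standard error of 1.28 (edgeR adjusted p = 7.86e-05). The chimpanzee libraries themselves ranged from 35.1 to 5555 CPM for this gene, and all 4 exons went the same way. Without chimpanzee replicate 1, the library at 5555 CPM, the log2 fold change was 7.56, slightly below the 7.62 of ENSG00000105193 in the same fit, so its first place rests on that library. The next tested gene along the chromosome, from 77161297 to 77162994 and 13.6 kb away, also rose, with a log2 fold change of 6.77 and a standard error of 0.96 (edgeR adjusted p = 7.10e-05). Its mean was 644 CPM in chimpanzee and 5.72 CPM in rhesus macaque. The tested gene before it on the chromosome had 19.3 and 23.2 CPM and did not pass (edgeR adjusted p = 0.631). ENSG00000105193, on chromosome 19 from 44616002 to 44616241, stood at 621 ± 156 CPM in chimpanzee and 3.17 ± 1.63 CPM in rhesus macaque (SD, n = 6 each), a log2 fold change of 7.58 with a standard error of 0.35 (edgeR adjusted p = 6.10e-09). This value rests on a single exon of 240 bases. Its neighbours on both sides, with 15 and 25 counted exons, did not pass the test.

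Towards rhesus macaque, the largest differences of this kind were in genes with a single counted exon. ENSG00000208978, on chromosome 5 from 123018501 to 123018910, fell from 2024 ± 974 CPM in rhesus macaque to 5.08 ± 3.61 CPM in chimpanzee (SD, n = 6 each), a log2 fold change of -8.69 with a standard error of 0.59 (edgeR adjusted p = 1.73e-07). The tested gene 37.9 kb before it went the other way, with a log2 fold change of 1.09. ENSG00000115523, on chromosome 2 from 85779198 to 85779385, had 2165 ± 705 CPM in rhesus macaque and 8.78 ± 15.5 CPM in chimpanzee (SD, n = 6 each), a log2 fold change of -7.93 with a standard error of 0.99 (edgeR adjusted p = 2.63e-05). One of its 6 chimpanzee libraries, replicate 4, held 39.7 CPM and replicate 1 held 0. Without chimpanzee replicate 4 its log2 fold change was -9.67, beyond the -8.61 of ENSG00000208978 in the same fit. A level that rests on 1 exon of 410 or 188 bases reflects reads assigned to that exon, and reads shared with a similar sequence elsewhere were not tested here. The same limit holds for ENSG00000105193, with 1 exon of 240 bases.

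**Figure D1:**
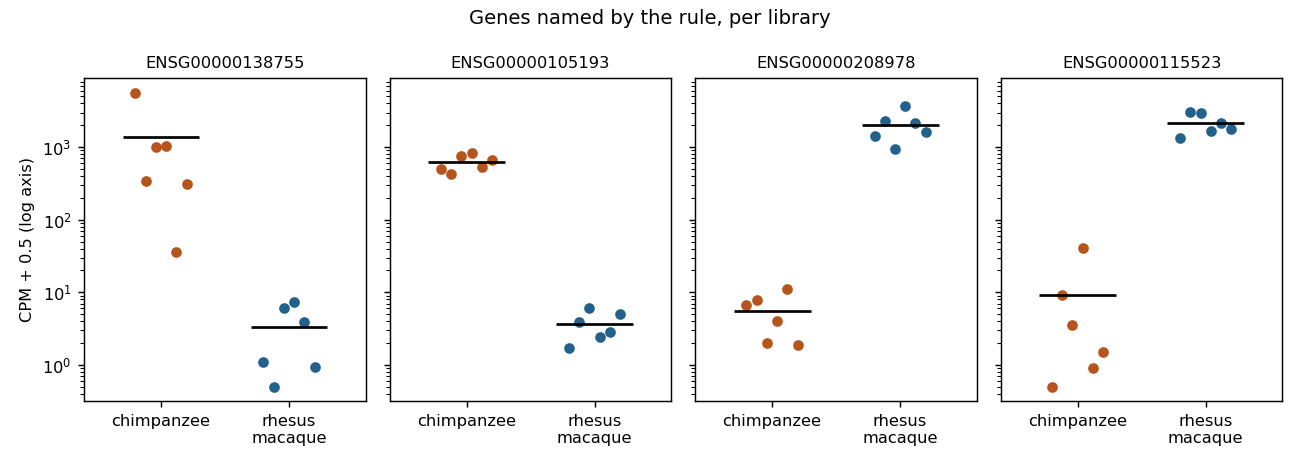
Level of the 4 identified genes in each library, as CPM plus 0.5 on a log axis, with points for the 6 libraries of each species and a black line at the species mean plus 0.5. All 12 libraries are separated by species in each panel, and chimpanzee libraries spread from 35.1 to 5555 CPM for ENSG00000138755.

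Some genes were read in 1 species only. Of the tested genes, 23 had 0 counts in all chimpanzee libraries and 6 had 0 counts in all rhesus macaque libraries. All of them passed the test, but the expression filter left little room for another outcome. It keeps a gene at 0 in 1 species only with enough counts in all 6 libraries of the other. The most abundant of the first kind lies on chromosome 12 from 89881591 to 89922934, with 6 counted exons, and stood at 930 ± 204 CPM in rhesus macaque (SD, n = 6), at least 5178-fold higher than the floor of 3 counts over the chimpanzee libraries. A gene with 5 counted exons on chromosome 3, from 150569495 to 150578258, had 224 ± 228 CPM in rhesus macaque, with libraries from 48.8 to 637 CPM, and was at least 1250-fold higher there. Another, with 8 counted exons on chromosome 2 from 96907354 to 96997091, had 143 ± 63.9 CPM and was at least 799-fold higher. In the other direction the most abundant gene, with 15 counted exons on chromosome 10 from 85944386 to 85967099, had 31.0 ± 15.4 CPM in chimpanzee, at least 177-fold above the floor of the rhesus macaque libraries. Single-exon genes on chromosome 6 from 49861606 to 49862859 and on chromosome 3 from 25340972 to 25341157 had 19.2 ± 9.19 and 17.4 ± 3.39 CPM in chimpanzee. A count of 0 in these files means that no read was assigned to the exon, and how exons were matched between the species is not given in the sources used here.

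Along the chromosomes of the shared coordinates, genes of chromosome 19 stood lower in chimpanzee as a set. Of its 638 tested genes, 66 were higher and 283 lower in chimpanzee, with a median log2 fold change of -0.58 (camera adjusted p = 1.83e-06, over 23 chromosomes). With an estimated correlation between genes the call was lost (camera adjusted p = 0.591 with an estimated correlation). No other chromosome passed. The medians of chromosomes 13 and 18 were 0.40 and 0.39, with 50 higher and 20 lower genes of 144 on chromosome 13 and 42 higher and 21 lower of 132 on chromosome 18. Chromosome medians fell with the number of tested genes per Mb (Spearman's rho = -0.770 across 23 chromosomes, permutation p = 3e-05, adjusted over 4 relations p = 3e-05). The same chromosomes separated libraries within a species. Chromosome 19 genes of chimpanzee replicate 1 lay 0.66 below the chimpanzee mean on the log2 scale (a deviation of -0.66), and those of rhesus macaque replicates 5 and 6 deviated by -0.24 and -0.25. Without these 3 libraries, 2498 genes were higher and 2328 lower in chimpanzee, and the chromosome 19 median was -0.63.

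**Figure D2:**
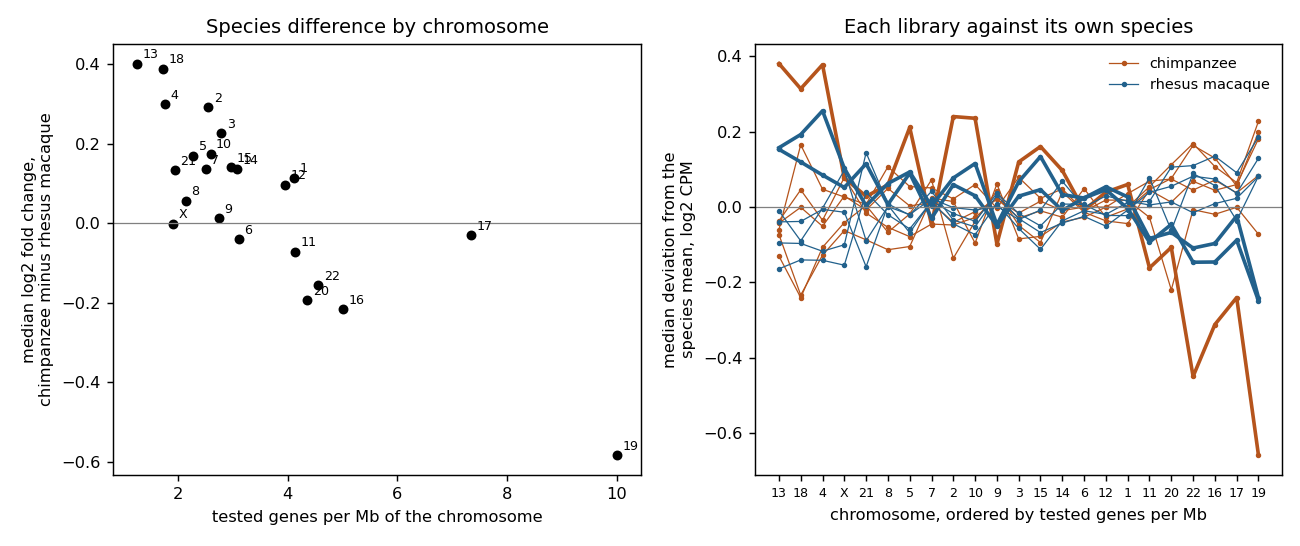
Left, the median log2 fold change of each chromosome (chimpanzee minus rhesus macaque) against its number of tested genes per Mb, with chromosome 19 lowest at -0.58. Right, the median deviation of each library from its species mean per chromosome in log2 CPM, with thick lines for chimpanzee replicate 1 and rhesus macaque replicates 5 and 6, which deviate by -0.66, -0.24 and -0.25 on chromosome 19.

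Neighbouring genes differed in the same direction more often than shuffled orders gave. There were 34 runs of at least 4 neighbouring genes, 18 higher and 16 lower in chimpanzee, holding 154 genes. When gene order was shuffled within chromosomes, the median number of runs was 17 and the highest 32 (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). The run with the largest median lay on chromosome 12 from 111829228 to 112020216, where 4 genes had log2 fold changes from 3.37 to 9.11. Their mean levels ran from 166 to 423 CPM in chimpanzee and from 0.763 to 30.9 CPM in rhesus macaque, and all 4 separated the species fully. On chromosome 7 from 28494318 to 30510977, 6 genes were higher in chimpanzee, with a median log2 fold change of 3.79. On chromosome 1 from 111461478 to 111587583, 4 genes had between 86.3 and 128 CPM in chimpanzee and between 2.81 and 46.0 CPM in rhesus macaque.

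In the other direction, 4 genes on chromosome 5 from 81319134 to 81718091 had log2 fold changes from -11.14 to -1.46, with between 5.93 and 641 CPM in rhesus macaque and between 0.0642 and 4.91 CPM in chimpanzee. On chromosome 6 from 123158521 to 126124108, 4 genes fell with a median of -3.32. On chromosome 19 from 56566686 to 56900254, 6 genes fell with a median of -3.05, the lowest at -7.04. The log2 fold changes of adjacent genes up to 10 kb apart had a Spearman correlation of 0.260 over 2186 pairs (shuffled median 0.0385, permutation p = 0.001, adjusted over 6 distances p = 0.0015). For pairs 10 to 50 kb apart it was 0.171, and for pairs over 1 Mb apart -0.00703. Pairs of genes are not independent replicates, and 37 other splits of the libraries, with 3 of each species on both sides, gave a median correlation of 0.183, with 5 of them at 0.260 or above. Without rhesus macaque replicate 6 there were 55 runs.

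**Figure D3:**
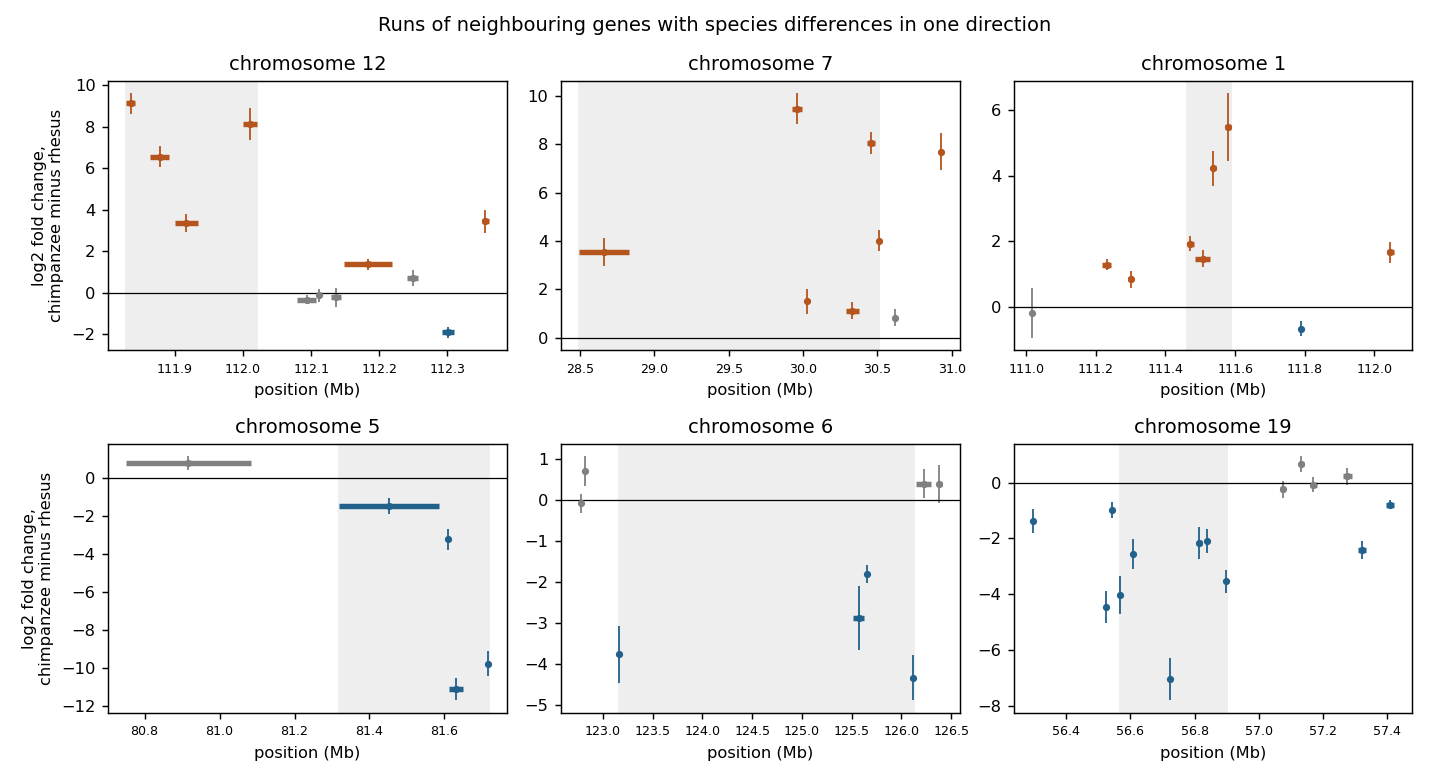
Log2 fold change (chimpanzee minus rhesus macaque) with its standard error for tested genes in and up to 0.5 Mb around 6 runs, by position in Mb. Grey areas mark the runs, horizontal bars the span of each gene, and orange, blue and grey points genes higher, lower or not called in chimpanzee, with medians from -6.50 on chromosome 5 to 7.33 on chromosome 12.

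**Figure D4:**
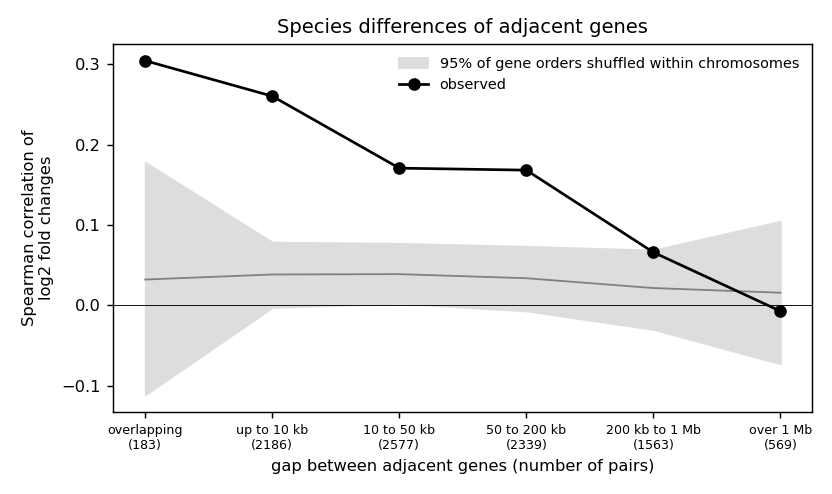
Spearman correlation of log2 fold changes between adjacent genes by the gap between them, with the number of pairs, beside the median (grey line) and central 95% (grey area) of 1000 shuffled gene orders. The observed value falls from 0.304 for overlapping genes to -0.00703 beyond 1 Mb.

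The use of single exons within genes was compared next, with the level of the gene taken out. Of 9970 genes with at least 2 tested exons, 445 (4.46%) held an exon whose share differed between the species (edgeR diffSpliceDGE, Simes method, adjusted p under 0.05). Taken one by one over all 87939 tested exons, 764 exons were called (exon-level adjusted p under 0.05). Of these, 480 had a higher and 284 a lower share in chimpanzee, and they need not all lie in the 445 genes. The strongest was an exon of 1910 bases on chromosome 8 from 25324627 to 25326536, which took 18.5% ± 4.78 of the gene's counts in rhesus macaque and 0.0449% ± 0.110 in chimpanzee (SD, n = 6 each), while the gene's own level did not pass the test. That exon had 1 count in chimpanzee and 574 in rhesus macaque. An exon of 1577 bases on chromosome 3 from 44374713 to 44376289 went the other way, at 44.7% ± 8.60 in chimpanzee and 0.179% ± 0.439 in rhesus macaque. This gene, too, had no called difference in level, and its exon had 175 counts in chimpanzee and 1 in rhesus macaque. On chromosome 11 from 10777336 to 10777547, the exon numbered 1 of a gene held 0.886% ± 0.588 of the counts in chimpanzee and 9.16% ± 1.25 in rhesus macaque. Another on chromosome 3, from 47893414 to 47894017, held 0.0598% ± 0.0669 in chimpanzee and 6.71% ± 0.734 in rhesus macaque. In the next gene, on chromosome 2, the exon with the smallest p, 1982 bases from 218917775 to 218919756, held 48.9% ± 9.76 in chimpanzee and 1.93% ± 2.65 in rhesus macaque (edgeR exon adjusted p = 3.20e-13). The exon of largest difference in that gene, from 218896162 to 218896398, held 2.02% ± 1.0 in chimpanzee and had 0 of 849 counts in rhesus macaque, which allows a share of up to 0.353% (edgeR exon adjusted p = 0.00265). An exon of 75 bases on chromosome 2 from 230990550 to 230990624 held 9.68% ± 2.3 in chimpanzee and 0.340% ± 0.245 in rhesus macaque. The 4 genes from chromosome 11 onwards also differed in level (edgeR adjusted p = 0.0437, 0.0170, 0.0162 and 0.0203). Of the genes called for exon usage and tested for level, 53.8% also differed in level, against 47.6% of other genes (Fisher's exact test, two-sided, p = 0.0122, over genes, which are not independent replicates). The level of a gene is the sum of the same exons, so the 2 calls are not independent. The gene-level F test called 1688 genes, and leaving out chimpanzee replicate 3 or 4 or rhesus macaque replicate 2, 3 or 4 left 290, 279, 265, 263 and 292 genes.

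Females and males were compared within each species by the sex given in the labels, which was not checked against the data. The files list no chromosome Y exons, so genes of that chromosome were not tested. In the simulated counts, 4-fold changes were called for 56.2% of genes in chimpanzee and 28% in rhesus macaque. For 2-fold changes the shares were 0% and 2%, so smaller sex differences would mostly be missed. No gene passed in chimpanzee (3 against 3) or in rhesus macaque (2 against 4) with the edgeR quasi-likelihood test, and 0 genes showed a different sex effect in the 2 species. At an unadjusted p under 0.05 there were 654, 206 and 479 genes, where 472 are expected by chance. Of the other 9 splits of the chimpanzee libraries into 3 and 3, 3 gave at least as many as 654, the highest 1468. DESeq2's Wald test called 50 genes in chimpanzee, 3 in rhesus macaque and 12 for the difference between the species. Chromosome X genes were not over-represented among the unadjusted genes, at 6.73% against 6.93% of other genes in chimpanzee and 3.37% against 2.14% in rhesus macaque (Fisher's exact test, two-sided, p = 1 and p = 0.155). Chromosome X took 2.64% ± 0.0804 of counts in chimpanzee females and 2.46% ± 0.140 in males (SD, n = 3 each, exact permutation test, two-sided, p = 0.2, where the smallest possible is 0.1). In rhesus macaque the shares were 2.81% ± 0.352 in 2 females and 2.79% ± 0.241 in 4 males (exact permutation test, two-sided, p = 1, where the smallest possible is 0.0667). Between the species, chromosome X took 2.55% ± 0.141 of counts in chimpanzee and 2.79% ± 0.245 in rhesus macaque (SD, n = 6 each, exact permutation test, two-sided, p = 0.0649). Without chimpanzee replicate 2, edgeR called 3 genes in chimpanzee and 1 for the difference between the species.

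The spread between individuals was similar in size in both species. The median SD of log2 CPM per gene was 0.48 in chimpanzee and 0.45 in rhesus macaque (9440 genes, n = 6 each), and 56% of genes varied more in chimpanzee. This order depended on 1 library, since the chimpanzee median was 0.41 without chimpanzee replicate 1. Among genes with a mean of at least 50 CPM, the most variable between chimpanzees lay on chromosome 3 from 112794437 to 112796603, with an SD of 3.42 on the log2 scale against 2.68 in rhesus macaque. It was followed by a gene on chromosome 8 from 39890485 to 39902047, with an SD of 3.29 against 1.22. Next came a gene on chromosome 8 from 134118155 to 134156557, which ranged from 0.404 to 593 CPM between chimpanzees, with an SD of 3.3 against 0.35 in rhesus macaque. Between rhesus macaques the most variable gene, on chromosome 16 from 76408319 to 76571504, ranged from 0 to 800 CPM, with an SD of 4.72 against 1.99 in chimpanzee. A gene on chromosome 2 from 88942509 to 88942550 had an SD of 3.50 against 1.57, and a gene on chromosome 4 from 1150725 to 1155862, which ranged from 4.33 to 1700 CPM between rhesus macaques, had an SD of 3.36 against 2.21.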

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

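The chromosome and neighbour results, and all tests of them given here, were chosen after the data were seen. The relation with rhesus macaque replicates 5 and 6 and the neighbour correlation over balanced splits were set only once the result was seen.

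A library was marked when its gap to the nearest of the other 5 of its species exceeded Dixon's 95% critical share of the whole range. Of 32 groups of 6 values examined, 4 had such a library, where chance gives about 1.6. Chimpanzee replicate 6 had 4751954 counts, and the other chimpanzee libraries had at most 2576148. Chimpanzee replicate 1 had the lowest chromosome 19 deviation, at -0.66 on the log2 scale, against -0.07 to 0.23 in the others. For the run on chromosome 12, chimpanzee replicate 5 had a median of 7.44 on the log2(CPM + 0.5) scale, against 8.05 to 8.38 in the other chimpanzees. For the run on chromosome 19, rhesus macaque replicate 6 had a median of 4.57 on that scale, against 6.16 to 6.39 in the other rhesus macaques.

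The species counts were set against other splits of the 12 libraries into 6 and 6. Of 100 splits, 1, the real one, called as many as 4549 genes, and the highest other called 643, a split with 5 chimpanzees on one side. For differences beyond 2-fold 1 of 100 splits reached 1628 genes and the highest other gave 2. The real split thus ranked first for both, the smallest share that 100 splits can give. Every other split mixed the species, so the species difference added to the spread on each side and left little room for calls. The distance to the other splits is therefore not a measure of the error rate, and chance is not excluded by it. For sex in chimpanzee the real split called 0 genes, so all 10 of 10 splits reach it by construction (the highest other called 1), and the splits decide nothing there.

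Chromosome 19 genes were lower in chimpanzee, by 0.62 relative to all genes (a difference of -0.62). Of 100 splits, 1, the real one, lay as far out, but the highest other, with 5 chimpanzees on one side, lay close at -0.58. The call as a set is lost with an estimated correlation between genes (camera adjusted p = 0.591). Chimpanzee replicate 1 alone is argued against by a median of -0.53 without it, and a trend with local gene density as the whole cause by a median of -0.37 after that correction (-0.58 before). What stays open is a library trend that also separates individuals, since the chromosome medians followed the difference between rhesus macaque replicates 5 and 6 and the other 4 (Spearman's rho = 0.861 across 23 chromosomes). Without chimpanzee replicate 1 and rhesus macaque replicates 5 and 6 the median was -0.63. Without rhesus macaque replicates 5 and 6 only, which lay towards chimpanzee on chromosome 19, the median was -0.69. Leaving them out thus deepened the shift, while leaving out chimpanzee replicate 1 lessened it, and the -0.63 joins both. The shift does not rest on these libraries alone, but such a trend between the remaining libraries is not excluded. The species themselves stay among the open explanations, and GC content was not tested.

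Neighbouring genes differed between the species together, in 34 runs. Of 100 splits, 1 gave as many runs and the highest other gave 0, but runs need called genes, which other splits mostly lack, so the shuffled gene orders are the sharper comparison. Chromosome-wide shifts and local gene density as whole causes of the correlation are argued against, with correlations of neighbours up to 10 kb of 0.218 after chromosome medians were subtracted and 0.203 after the density correction. Without overlapping genes there were 34 runs. After the density correction there were 27, for which no shuffled orders were drawn, so the number of runs is not settled by that correction. In the 37 splits with 3 libraries of each species on both sides, which carry no species difference, the correlation ran from 0.104 to 0.352 and 5 of them reached the 0.260 of the species split. Neighbours that vary together between individuals of any species may therefore account for part or all of the correlation, while the size of the differences in the runs is left open, with the species among the explanations.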

How the results depend on the processing

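Of 95 values of the main results under other settings, 83 kept their side of the limits (counts within 1.5 times), and of 132 values with 1 library left out 123 did. The chromosome and neighbour results, the density correction and the fits without 2 or 3 libraries were added after the data were seen. Genes beyond 2-fold rose to 2800 with no expression filter, where 16903 genes were tested, and the species counts fell to 1371 and 1385 with males only, where 7 libraries were left. The higher share among calls stayed between 48.9% and 52.4%, and no gene shared with the reported calls changed sign except 2 genes without the strongest exon. The share of the 4549 reported calls that was kept ran from 55.4% with males only to 99.6% with DESeq2's Wald test. It was 76.6% without the strongest exon, 86.2% after the density correction, 86.8% when thinned and 91.3% on exons seen in at least 3 libraries of each species. The 4 identified genes kept direction and call in the fits that tested them, at adjusted p up to 0.00421 (edgeR, DESeq2 or limma). Removal of the strongest exon gave no value for them, since 3 have a single counted exon and ENSG00000138755 no longer passed the expression filter. Chromosomes with a shifted set were 0 with an estimated correlation and 16 with fry, which does not compare a set with other genes. Runs numbered 149 and 11 at minimum lengths of 3 and 5, 72 without rhesus macaque replicates 5 and 6, and 24 to 55 with 1 library left out. Exon usage gave 1688 genes with the gene-level F test and 263 to 540 with 1 library left out. DESeq2's Wald test for sex gave 50, 3 and 12 genes, and leaving out 1 library 0 to 3 in chimpanzee and 0 to 1 for the difference between the species. The median SD in chimpanzee was 0.41 to 0.51 with 1 library left out. The cause was not tested for the F test, fry, Wald and leave-one-out values. The gene lists were not run, since the files hold no symbols. Thinned to the smallest library, 2068 and 2011 genes were higher and lower in chimpanzee. No paired analysis was possible because replicate numbers follow the order of the records and separate individuals make up each species.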

Other observations

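The lists of positions, the counts of variable genes and the tests of exon position in this part were chosen after the data were seen, and the splits and shared-exon test of exon usage before.

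Chromosome 19 held 5 of the 34 runs, all lower in chimpanzee. Beside the run described above, 4 genes from 5629433 to 5735251 on chromosome 19 fell with a median log2 fold change of -2.78 and 6 genes from 2884217 to 3131329 with a median of -1.86. Chromosome 3 held 4 runs, all higher in chimpanzee, among them 5 genes from 172262986 to 174021957 with a median of 2.37. On chromosome 2 from 159533392 to 161800978, 7 genes in a row were higher in chimpanzee, with a median of 2.42. On chromosome 17 from 71334905 to 71445908, 6 genes were lower, all 6 fully separated between the species. Chromosome X held 3 runs, 2 of them higher in chimpanzee, from 37524239 to 40350830 and from 153952889 to 154802738.

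Genes that varied widely between individuals tended to be shared by the species. An SD above 1 on the log2 CPM scale was found for 1026 genes in chimpanzee and 825 in rhesus macaque, and 365 genes had it in both, where independent lists would share 89.7. Among genes with a mean of at least 50 CPM in both species, 161 had it in chimpanzee and 97 in rhesus macaque, with 40 in both against 4.27 for independent lists.

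Exons read in 1 species only were about as frequent in either direction. There were 366 exons with at least 50 counts in chimpanzee and 0 in rhesus macaque, and 381 of the reverse kind. Only 23 and 21 of these lay in genes with at least 50 counts in both species. Exons called for usage were the first or last counted exon of their gene in 36.4% of 764 cases, against 20.4% of other exons (Fisher's exact test, two-sided, p = 4.14e-24, over exons, which are not independent replicates). In a gene with few counted exons a larger part of them are first or last, and exons with more counts are easier to call. The comparison was matched for neither, so it does not show a preference for position.

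Genes with different exon usage are a further pattern that was weighed. Of 25 splits of the 12 libraries, 1, the real one, called as many as 445 genes and the highest other called 6. This is the smallest share that 25 splits can give. The other splits mixed the species, so the species difference added to the spread on each side and left little room for calls. They therefore do not give the error rate of the exon test, and chance is not excluded by them. On exons seen in at least 3 libraries of each species, 391 genes (87.9% as many) were called, 341 of them among the reported 445. Exons with no reads at all in 1 species are thus argued against as the main cause. A single count per library was enough there, so a poor match in the other genome that leaves a few reads is not excluded. The chromosome 8 exon and the first chromosome 3 exon of the Results, with 1 count in chimpanzee and in rhesus macaque respectively, fall outside that set. Exons seen in 1 species only may account for a part, as 10.6% of called exons (32 in chimpanzee and 49 in rhesus macaque) had 0 counts in 1 species, against 3.78% of tested exons. Exons that align in both genomes with unequal ease were not tested here, nor was reference sequence divergence, and the species themselves stay open.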
